A study of Mus musculus with 6 samples.

How the data were processed

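Single-cell RNA was measured in 6 mouse colonic tumours, 3 labelled Apc ICI and 3 labelled AOM PN, with 1 library per tumour. Per the labels' protocols, whole tumours of male mice were dissociated mechanically and enzymatically, dead cells were removed by flow sorting on DAPI, and droplet-based 3′ libraries with unique molecular identifiers (UMIs) were sequenced on an Illumina instrument. The authors deposited raw UMI counts per gene and barcode, made with Cell Ranger 6.1.2 against the mm10 genome, per the submitters' processing notes. Each deposited count table held 31053 features, and 35 gene symbols were shared by more than 1 feature, so features were kept apart by their identifiers. Every deposited barcode carried at least 500 UMIs. The gene annotation and the rule by which cells had been called were not given in the sources used here.

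Library totals were 59403877, 59309093 and 60075436 UMIs in Apc ICI 1, 2 and 3 and 87107277, 88426376 and 98583066 in AOM PN 1, 2 and 3. Haemoglobin transcripts took 42.8%, 21.4% and 61.4% of the UMIs in the Apc ICI libraries and 25.5%, 29.0% and 1.87% in the AOM PN libraries. A chi-square test over genes gave at least 187 per degree of freedom for each pair of libraries, so no library was a copy of another. The labels describe separate samples and do not say whether each came from a different animal, so p-values measure the spread between these samples. Intervals and limits for counts of 0 cover counting error only.

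Barcodes with at least 200 genes and at most 20% mitochondrial UMIs were kept. Doublets were scored against simulated doublets within each library, and a share of barcodes set by an expected 0.8% per 1000 barcodes was removed, 5.50% to 12.9% of the barcodes that passed the filters. This left 4726, 6804 and 4905 cells in the Apc ICI libraries and 10168, 8060 and 11399 in the AOM PN libraries. Counts without haemoglobin were scaled to 10000 per cell and log-transformed, and 2000 variable genes were reduced to 30 principal components. Cells were clustered with the Leiden algorithm (leidenalg 0.10.2, igraph 0.11.9) at resolution 1 on 20 nearest neighbours, without correction for batch. This was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0. Clusters with epithelial markers were pooled and clustered again. No annotation of cells was used from the authors, so a cluster was called "X-like" from marker genes of 13 cell classes fixed beforehand, and needed at least 3 detected markers. Names were rebuilt here and can differ from those of the study. A marker counted as detected with a UMI in at least 10% of the cluster's cells and a log2 fold of at least 1 over the median cluster. Some naming rules were set after the clusters had been seen. Leading genes were ranked against the unweighted mean of the other clusters with a pseudocount of 1 per 10000, in place of all other cells pooled. A cluster led by Mcpt8 and Il4, genes of basophils, was left unnamed, as were sub-clusters of the epithelial pool led by at least 3 markers of another class. Unnamed cells made up 2.76% of the Apc ICI cells (454 of 16435) and 1.48% of the AOM PN cells (438 of 29627). No cluster could be named fibroblast-, endothelial-, pericyte- or glia-like, so these classes were not tested.

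UMI counts were summed per library and class, and sums of at least 20 cells entered the test. Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are log2 ratios of AOM PN over Apc ICI, with standard errors; levels are UMI counts scaled by effective library size (CPM), given as mean ± SD of the 3 libraries. Mast- and plasma-like cells were too few in Apc ICI for a gene test. Class shares were tested with edgeR on cell numbers with the kept cells as library size, and with a two-sided exact permutation test, whose smallest p for 3 against 3 is 0.1. The 36 gene lists were fixed beforehand, and those meant for fibroblasts and endothelium were not tested. The others were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. A member was marked as mainly of another class where its mean level was less than 0.25 of that in the highest other class. Shares of epithelial-like cells with a UMI of chosen genes were taken after thinning each cell to 1500 UMIs. On simulated counts with 200 changed genes, the edgeR script recovered 71% of 2-fold changes in the epithelial-like sums and 62% to 85% in the other classes. It recovered 99% to 100% of 4-fold changes, and 4.73% to 8.50% of its calls were false. The changed genes were drawn among those with higher counts, so weakly counted genes are not covered. The real data gave 4784 calls in epithelial-like and 3039 in neutrophil-like sums, and the simulation did not cover so many changes.

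Named genes followed a rule set with the design. They were the genes with the 8 largest changes in each direction in epithelial-like cells, and the 5 largest in other classes, among called genes of average log2 CPM of at least 4 whose groups did not overlap and whose level was at least 0.25 of that in any other class. Gene models without a symbol of their own, mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor and sex-linked genes were left out of that part. To these were added up to 3 list members with the smallest adjusted p, any opposite call, and 12 fixed epithelial genes. Other list members are named where a short count needed it, after their values had been seen. Some genes that the rule takes are not reported here.

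Alternatives listed before the data were examined were DESeq2 1.42.0, another normalization, no filter on low counts, the replicate number as a block, each library left out, doublets kept, at least 500 genes per cell, at most 10% mitochondrial UMIs, Leiden resolutions of 0.5 and 2, class sums thinned to 1 total, other camera settings, other denominators and other depths for thinning. Another 4 were added after the data had been seen: at least 1000 genes per cell, mitochondrial shares of 1% to 20%, cells of at least 1500 UMIs alone, each thinned to 1500 before summing, and shares without erythroid-like cells. Interaction tests between classes and tests on RNA of other classes were also added then.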

Results

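Tumours of 2 mouse models of colon cancer were compared by droplet-based single-cell RNA sequencing, with 3 tumours per model. In the Apc ICI model, both alleles of Apc, a brake on Wnt signalling, are floxed under an inducible villin Cre. Recombination was induced locally by injecting 70 µl of 100 µM hydroxytamoxifen into the colonic submucosa. In the AOM PN model, the same Cre acts on floxed p53 (Trp53) and a Notch1 transgene after 2 mg of systemic tamoxifen. These mice then received the colon carcinogen azoxymethane (AOM) from day 4, at 10 mg/kg weekly for 6 weeks. The comparison asks how tumours of the Apc ICI model differ from those of the AOM PN model, in the epithelium and in the immune cells around it. The models differ in the targeted genes, in the carcinogen and in how recombination was induced. Effects of these cannot be told apart here. The labels give no batch, and a batch shared by the libraries of a model could not be told apart from the model either. Library totals split by group, at 59309093 to 60075436 UMIs in Apc ICI and 87107277 to 98583066 in AOM PN. The libraries held 59309093 to 98583066 unique molecular identifiers (UMIs), and 16435 cells were kept from Apc ICI and 29627 from AOM PN.

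Mast-like cells made up a larger share of AOM PN than of Apc ICI tumours. They took 0.324% ± 0.0378 (SD, n = 3) of the kept cells in Apc ICI and 11.6% ± 9.14 (n = 3) in AOM PN. The lowest AOM PN value was 2.73% and the highest Apc ICI value 0.367%. The log2 change was 5.15 ± 0.82 (edgeR adjusted p = 0.000803; 4.40 without AOM PN 3). Plasma-like cells rose from 0.0771% ± 0.0311 to 0.368% ± 0.255 (log2 change 2.26 ± 0.70, edgeR adjusted p = 0.0417), on 12 cells in Apc ICI. The edgeR call was lost without Apc ICI 1 (adjusted p = 0.0628), Apc ICI 2 (0.142), Apc ICI 3 (0.123) or AOM PN 1 (0.160, with a change of 1.53). The two-sided exact permutation test gave p = 0.1 for both classes, the smallest it can give for 3 against 3. The exact test gave p = 0.1 also for T/NK-, dendritic-, epithelial- and monocyte/macrophage-like cells, and 0.4 for B-, 0.2 for erythroid- and 0.6 for neutrophil-like cells.

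The other classes did not pass the edgeR test of shares. Neutrophil-like cells made up 39.1% ± 14.5 of cells in Apc ICI and 33.2% ± 10.8 in AOM PN (n = 3 each). T/NK-like cells made up 4.68% ± 2.34 and 12.5% ± 3.82 (edgeR adjusted p = 0.0898), and monocyte/macrophage-like cells 12.9% ± 3.90 and 22.9% ± 1.53 (0.152). Epithelial-like cells made up 13.6% ± 1.93 and 7.07% ± 2.59 (0.145), and B-like cells 2.89% ± 2.06 and 1.31% ± 1.21 (0.196). Dendritic-like cells took 1.78% ± 0.810 and 4.44% ± 1.65, and erythroid-like cells 22.0% ± 15.9 and 5.22% ± 5.44 (0.0979 each). Shares were taken after a sort that removed dead cells with DAPI and from barcodes of at least 500 UMIs. Epithelial-like cells had median depths of 4806, 7619 and 3226 UMIs in Apc ICI 1, 2 and 3, against 1114, 1624 and 1371 in AOM PN 1, 2 and 3. T/NK-like cells passed the edgeR test without Apc ICI 1 (adjusted p = 0.0399), B-like cells without AOM PN 3 (0.0336) and erythroid-like cells without AOM PN 1 (0.00239). The neutrophil-like change turned to 0.11 without Apc ICI 2.

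**Figure D1:**
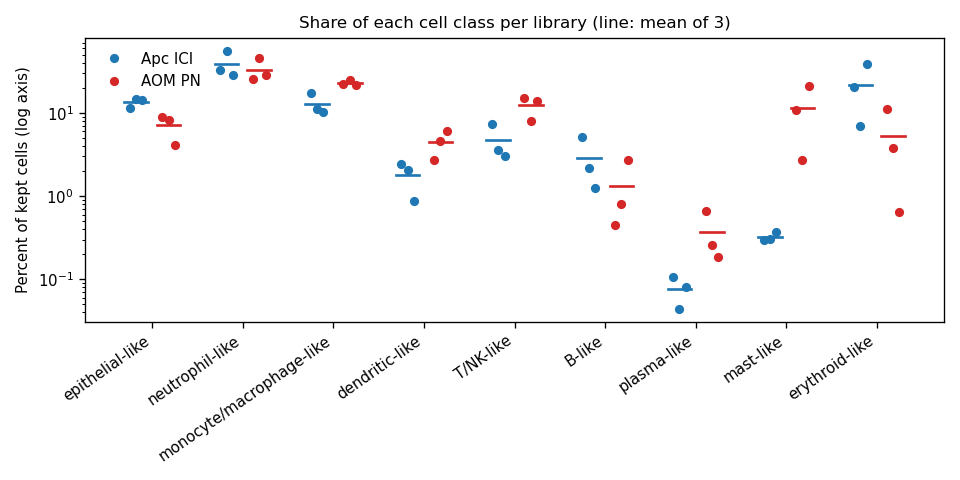
Share of each cell class in percent of kept cells (vertical axis, log scale) per library, with a line at the mean of 3 libraries, for Apc ICI and AOM PN. The mast-like shares lie at 0.296% to 0.367% in Apc ICI and at 2.73% or more in AOM PN.

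The targeted genes were read first, in epithelial-like cells. Trp53 (ENSMUSG00000059552) was at 135, 152 and 153 CPM in Apc ICI 1, 2 and 3 and fell to 50.9, 70.5 and 55.9 CPM in AOM PN 1, 2 and 3 (log2 change -1.30 ± 0.17, edgeR adjusted p = 0.000305). Notch1 (ENSMUSG00000026923) rose from 34.5 ± 3.06 to 66.0 ± 16.9 CPM (0.91 ± 0.20, edgeR adjusted p = 0.00476). Apc (ENSMUSG00000005871) was at 78.2 ± 7.81 CPM in Apc ICI and 70.3 ± 10.9 in AOM PN (-0.16 ± 0.17, edgeR adjusted p = 0.477). The labels do not state which exons are deleted or which part of Notch1 the transgene carries. A 3′ tag outside a deleted part checks nothing, so these values do not test the labels.

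Sums of AOM PN epithelial-like cells held more of the antimicrobial lectin Reg3b, the acute-phase gene Saa1 and Nos2, the inducible nitric oxide synthase. Sums of Apc ICI epithelial-like cells held more of the Paneth cell lysozyme Lyz1 and of Ang4. A sub-cluster led by Lypd8, Saa1 and Reg3b held 87 AOM PN and 9 Apc ICI cells, 4.27% and 0.399% of the class (6.49% without AOM PN 1 and 0.232% without Apc ICI 1). Clca4b, Clca4a and Krt20 were among its leading genes within the epithelial cells. Of 12119 genes tested, 2483 rose and 2301 fell in AOM PN at an edgeR adjusted p under 0.05. Groups did not overlap for 52.9% of genes, against 10% by chance. Ceacam20 rose from 0.305 ± 0.166 to 46.3 ± 16.9 CPM (log2 change 7.14 ± 0.42), Clca4b from 0.508 ± 0.213 to 135 ± 99.7 (8.12 ± 0.87), and Nos2 from 1.68 ± 0.762 to 92.0 ± 28.3 (5.85 ± 0.33). Clca4a was seen as 3 UMIs in Apc ICI and 479 in AOM PN. Saa1 rose by 6.72 ± 1.03 (5.18 without AOM PN 2) and Reg3b by 6.23 ± 0.70 (5.46 without AOM PN 2, 6.87 without Apc ICI 3). Gsdmc2 rose by 6.00 ± 1.08 (3.96 without AOM PN 3, 7.80 without Apc ICI 2), and the ubiquitin-like gene Ubd by 5.05 ± 0.71 (4.23 without Apc ICI 2, 7.09 without Apc ICI 3).

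A sub-cluster led by Spink4, Defa24 and Lyz1 held 101 Apc ICI and 9 AOM PN cells, 4.47% and 0.442% of the class. At the other end, 5 of the 8 named epithelial genes that fell had no UMI in AOM PN epithelial-like cells. Lyz1 was at 98.3, 1079 and 549 CPM in Apc ICI 1, 2 and 3. In counts summed over each group it was at 744 CPM in Apc ICI, at least 1613-fold above the limit of 3 counts in AOM PN, which is 0.461 CPM (at least 673-fold without Apc ICI 2). All limits of this kind are ratios of summed counts, not of the mean of libraries. The Paneth defensin Defa24 was at 9.42, 705 and 18.1 CPM in Apc ICI 1, 2 and 3. Its call was lost without AOM PN 1, 2 or 3 (edgeR adjusted p = 0.0636, 0.0732 and 0.0633), and its close paralogs make its counts uncertain. Bex4 was at least 92.7-fold, the pancreatic colipase Clps at least 73.9-fold and Gas1 at least 57.7-fold lower. Without AOM PN 2 these limits were 45.0, 35.9 and 28.0. Podn and Alb, which encodes albumin, were seen as 1 UMI each in AOM PN against 1289 and 1030 in Apc ICI. Ang4 was at 128 ± 106 CPM in Apc ICI and at 0, 0 and 2.90 CPM in AOM PN 1, 2 and 3.

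Wnt target genes moved in both directions. Of 22 members measured, 1 of them mainly of another class, 9 fell and 5 rose (10 and 5 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.143). The Wnt inhibitor Wif1 fell from 660 ± 198 to 12.7 ± 5.15 CPM (log2 change -5.78 ± 0.36). Dkk3 was seen as 2 UMIs in AOM PN against 1630 in Apc ICI. The Eph receptor Ephb3 rose by 2.73 ± 0.19 and the transcription factor Myc by 1.67 ± 0.18. Among markers of crypt base stem cells, 8 of 15 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.0933). Lrig1 rose by 3.06 ± 0.19 and Scn2b by 2.21 ± 0.23, while Smoc2 fell by 2.80 and Mex3a by 2.35. Lgr5, a receptor that marks these cells, was at 50.4 ± 19.3 CPM in Apc ICI and 45.8 ± 1.42 in AOM PN (edgeR adjusted p = 0.723). The stem cell factor Ascl2 was at 30.6 ± 14.1 and 32.0 ± 6.27 CPM (edgeR adjusted p = 0.944).

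Genes of fetal and regenerating epithelium included 8 that rose and 3 that fell of 19 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0933), and 7 members were mainly of another class. The EGF receptor ligand Areg rose by 3.61 ± 0.32, and Ereg by 6.81 ± 0.64 (9.72 without Apc ICI 2). Ly6a, the Sca-1 antigen, rose from 108 ± 41.3 to 631 ± 220 CPM (2.55 ± 0.36, edgeR adjusted p = 0.000385). Il1rn rose by 2.53 ± 0.18. Areg was higher in T/NK-like cells, and Il1rn in neutrophil-like cells, than in epithelial-like cells. Clu rose by 0.78 ± 0.25 (edgeR adjusted p = 0.031). That call was lost without Apc ICI 2 (0.133), Apc ICI 3 (0.103), AOM PN 1 (0.0657) or AOM PN 2 (0.112). Anxa1 was at 242 ± 58.5 and 309 ± 161 CPM (edgeR adjusted p = 0.415). Of 17 YAP/TAZ targets 6 rose and 3 fell, also when adjusted over the list alone (5 mainly of another class; camera adjusted p = 0.200). Crim1 rose by 4.18 ± 0.28, Nt5e by 2.25 ± 0.27 and Nuak2 by 2.18 ± 0.23, while Igfbp3 was at least 17.5-fold lower (at least 8.49-fold without AOM PN 2).

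Of 7 Notch pathway genes measured 4 rose and none fell, also when adjusted over the list alone (camera adjusted p = 0.0187; adjusted p = 0.536 with an estimated correlation). The feedback regulator Nrarp rose from 5.29 ± 2.27 to 111 ± 16.3 CPM (4.33 ± 0.29), the ligand Jag1 by 2.16 ± 0.28 and Dtx4 by 1.68 ± 0.30, beside Notch1. Hes1, a classical Notch target, was at 284 ± 53.1 and 367 ± 57.6 CPM (edgeR adjusted p = 0.172). Of 20 p53 targets 8 rose and none fell, also when adjusted over the list alone, and the list missed the threshold (4 mainly of another class; camera adjusted p = 0.0561). The kinase Plk2 rose by 2.50 ± 0.19, the death receptor Tnfrsf10b by 1.54 ± 0.32 and Ddit4l by 1.42 ± 0.29. Cdkn1a, the cell cycle inhibitor p21, was at 232 ± 42.7 and 258 ± 73.0 CPM (edgeR adjusted p = 0.649).

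**Figure D2:**
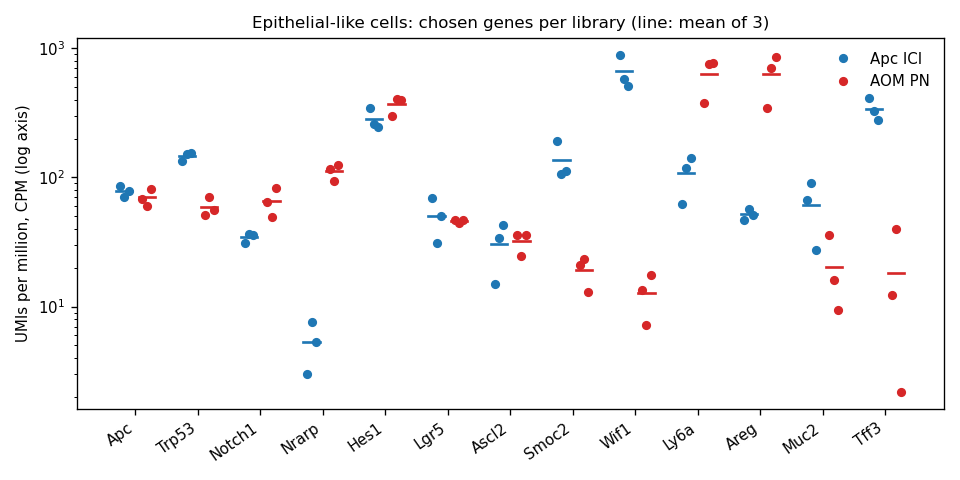
Level in epithelial-like cells, in CPM (vertical axis, log scale), of the targeted genes and of chosen Notch, stem cell, regenerative and goblet genes in each library, with a line at the mean of 3 libraries per group. Nrarp averages 5.29 CPM in Apc ICI and 111 in AOM PN, and Wif1 660 and 12.7.

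Goblet and secretory genes fell, 12 of 15 with none higher, also when adjusted over the list alone (3 mainly of another class; camera adjusted p = 0.000696; adjusted p = 0.536 with an estimated correlation). Tff3 and Muc2 were among the leading genes of the sub-cluster that held 101 Apc ICI and 9 AOM PN cells. The trefoil factor Tff3 fell by 4.05 (by 5.47 without AOM PN 2) and Bcas1 by 3.90. The goblet mucin Muc2 fell from 61.5 ± 31.6 to 20.4 ± 13.7 CPM (log2 change -1.61 ± 0.48; -2.21 without AOM PN 1). Its call was lost without Apc ICI 2 (edgeR adjusted p = 0.0658), AOM PN 2 (0.102) or AOM PN 3 (0.0838), and with doublets kept the change was 0.068. Absorptive colonocyte genes rose, 8 of 10 with 1 lower, also when adjusted over the list alone (1 mainly of another class; camera adjusted p = 0.00470; adjusted p = 0.567 with an estimated correlation). The sub-cluster with Krt20 and Clca4a held 9 Apc ICI and 87 AOM PN cells. Ceacam20 was among the genes that rose, and the carbonic anhydrase Car4 was seen as 3 UMIs in Apc ICI and 104 in AOM PN. Guca2a, which encodes guanylin, fell by 2.57. Of 4 gastric genes measured 3 fell, also when adjusted over the list alone: the protease Ctse by 4.33, Vsig1 by 1.84, and the gland mucin Muc6, at least 35.6-fold lower (at least 17.3-fold without AOM PN 2). The gastric list call (camera adjusted p = 0.0270; adjusted p = 0.536 with an estimated correlation) was lost without AOM PN 2 (adjusted p = 0.0527).

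Of 15 NF-κB targets and chemokines 8 rose and 1 fell in AOM PN epithelial-like cells (9 and 1 adjusted over the list alone), and 11 were mainly of another class (camera adjusted p = 0.0155; adjusted p = 0.567 with an estimated correlation). Icam1 rose by 2.26 ± 0.28, Tnf by 1.65 ± 0.26 and Cxcl2 by 1.46 ± 0.23, and Lcn2 fell by 2.89. All 7 MHC class II genes measured rose, also when adjusted over the list alone, and all were mainly of another class (camera adjusted p = 0.00242; adjusted p = 0.567 with an estimated correlation). H2-Ab1 rose from 14.9 ± 3.98 to 43.1 ± 11.4 CPM. In the same sums, 30 abundant transcripts of monocyte/macrophage-like cells stood at 0.488% ± 0.119 of their level in those cells in Apc ICI and 0.792% ± 0.216 in AOM PN. Those of neutrophil-like cells stood at 0.550% ± 0.108 and 1.01% ± 0.0344, and those of mast-like cells at 0.0979% ± 0.0143 and 1.45% ± 1.05. Of 16 immediate early and heat shock genes, which respond to dissociation, 8 rose, also when adjusted over the list alone (4 mainly of another class; camera adjusted p = 0.0166; adjusted p = 0.641 with an estimated correlation). Jun rose by 1.40 ± 0.23 and Dnajb1 by 1.26 ± 0.19, and the list call was lost without Apc ICI 3 (adjusted p = 0.0594).

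The remaining epithelial lists did not pass, and their counts adjusted over the list alone were those over all genes unless given. Of 16 interferon response genes 4 rose and 1 fell, and 14 were mainly of another class (camera adjusted p = 0.0933), with Irf7 higher by 2.49 ± 0.22 and Usp18 lower (-3.84 ± 0.32). Of 12 MHC class I genes 6 rose, and 9 were mainly of another class (camera adjusted p = 0.143), and of 22 cell cycle genes only Mki67 (1.28 ± 0.31; camera adjusted p = 0.217). Of 11 mesenchymal and invasion genes 3 rose and 4 fell (6 and 4 adjusted over the list alone; 2 mainly of another class; camera adjusted p = 0.813, median 0.53 and mean -0.28). Vim, which encodes vimentin, fell from 1366 ± 290 to 63.1 ± 24.0 CPM, Fn1 by 1.87 and Mmp14 by 1.74, and L1cam rose by 1.52 ± 0.27. Of 14 TGF-β targets 2 rose and 3 fell (6 mainly of another class; camera adjusted p = 0.748, median 0.13 and mean -0.09), with Smad7 at 1.35 ± 0.22 and Id3 at -0.93 ± 0.20. Of 15 hypoxia genes 3 rose and 2 fell (2 mainly of another class; camera adjusted p = 0.798); Bnip3 fell by 2.80 and Ndrg1 by 2.56, and Vegfa rose by 1.13 ± 0.20. Of 5 enteroendocrine and 4 tuft genes 1 rose and 1 fell in each list (1 in each mainly of another class; camera adjusted p = 0.748 and 0.989). The enteroendocrine test pointed down against a median of 2.22, and the tuft gene Avil fell by 3.03.

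Most epithelial-like cells of the groups lay in different sub-clusters. In 6 sub-clusters with Mt3 among their leading genes there were 462, 404, 414, 269, 95 and 142 Apc ICI cells and 25, 27, 0, 0, 0 and 77 AOM PN cells. Their median depths were 1116, 3189, 30195, 35741, 6861 and 1962 UMIs. Depth thus differed between sub-clusters, and its part in the split of the groups was not tested. In 2 sub-clusters led by Gm26917 with Tcim, Sox4 and Plk2 there were 31.7% and 23.5% of the AOM PN cells, and 1.20% and 0.310% of the Apc ICI cells (0.194% for the latter without Apc ICI 3). Their median depths were 890 and 1624.5 UMIs, with 1.57% and 3.15% mitochondrial UMIs. In the larger, Lars2 ranked next after Gm26917, and Plk2 and Ephb3 were among its leading genes within the epithelial cells. The smaller was set apart within the epithelial cells mostly by immediate early and heat shock genes (Jun, Egr1, Dnajb1, Ier2, Atf3 and Btg2). Plk2, named above among p53 targets, and Areg, named among regenerative genes, were also among its leading genes there. Gm26917, which led 6 of the named sub-clusters, 2 of them with Mt3, is a non-coding transcript and not an epithelial marker. The sums held 1336859 to 17571284 UMIs, and 628 of the 4784 called genes were mainly of another class. With sums of only the cells of at least 1500 UMIs, each thinned to 1500, 1220 genes rose and 926 fell, of 7046 tested.

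Shares of epithelial-like cells with a UMI were taken after thinning to 1500 UMIs. Ly6a was seen in 8.38% ± 1.35 of cells in Apc ICI and 23.3% ± 2.36 in AOM PN (n = 3 each, exact permutation p = 0.1), and Lgr5 in 8.85% ± 2.34 and 5.96% ± 1.53 (exact permutation p = 0.1). Ascl2 was seen in 4.31% ± 1.55 and 3.29% ± 0.359 (exact permutation p = 0.4), and Clu in 21.2% ± 6.68 and 29.6% ± 5.94 (0.2). Mki67 was seen in 5.24% ± 1.42 and 11.3% ± 4.76 (exact permutation p = 0.2), and Anxa1 in 20.2% ± 0.566 and 23.6% ± 5.80 (0.4). In T/NK-like cells thinned alike, the shares were 0% and 0.191% for Lgr5, 0.101% and 0.388% for Clu, 4.07% and 2.97% for Mki67 and 3.81% and 3.14% for Anxa1. Ly6a, which T cells express, was seen in 7.25% and 3.29% of monocyte/macrophage-like cells, with 3.68% to 12.97% over the Apc ICI libraries. Whether those UMIs were free RNA was not tested. Thinning used 1673 Apc ICI and 886 AOM PN cells and left out 584 and 1150. Without thinning the shares were 17.1% and 24.0% for Ly6a, 23.4% and 8.28% for Lgr5, and 17.4% and 5.68% for Ascl2. They were 37.1% and 29.1% for Clu, 13.3% and 11.7% for Mki67 and 40.6% and 24.7% for Anxa1, the reverse of the thinned direction.

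Neutrophil-like cells of AOM PN carried less Gpnmb, Gdf15 and Hmox1, and more Mmp9, Nfkbiz and Csf3. Of 9350 genes 1417 rose and 1622 fell (edgeR adjusted p under 0.05), and groups did not overlap for 49.0%, against 10% by chance. Of the calls, 1277 were of genes mainly of another class, 993 of them falls. Gpnmb, a lysosomal glycoprotein, fell from 62.1 ± 9.60 to 0.210 ± 0.244 CPM (log2 change -8.35 ± 0.44; -9.23 without AOM PN 1). The stress cytokine Gdf15 fell from 137 ± 37.8 to 1.22 ± 0.184 (-6.82 ± 0.30), and Nceh1 from 85.4 ± 11.2 to 4.61 ± 1.26 (-4.21 ± 0.24). Anxa6 rose by 3.43 ± 0.24, the protease inhibitor Serpinb2 by 2.65 ± 0.45, Kdm6bos by 2.64 ± 0.27 and the inhibitory lectin Clec12a by 2.42 ± 0.34. The numbers were 591 higher without Apc ICI 1 and 878 lower without Apc ICI 2.

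Interferon response genes fell in neutrophil-like cells, 11 of 17 with none higher, also when adjusted over the list alone (2 mainly of another class; camera adjusted p = 0.00383; adjusted p = 0.679 with an estimated correlation). The antiviral gene Oasl2 fell from 477 ± 182 to 24.4 ± 8.03 CPM. Ifit2 fell by 4.39 and Ifit3 by 3.92 (by 3.07 and 3.14 without Apc ICI 2). Of 16 NF-κB targets and chemokines 7 rose and 1 fell (11 and 2 adjusted over the list alone; 1 mainly of another class; camera adjusted p = 0.00282; adjusted p = 0.361 with an estimated correlation). Nfkbiz rose by 1.10 ± 0.20, Birc3 by 0.79 ± 0.15 and the neutrophil growth factor Csf3 by 2.06 ± 0.43 (1.39 without AOM PN 1). Of 14 genes of circulating neutrophils 3 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.00383; adjusted p = 0.543 with an estimated correlation). The gelatinase Mmp9 rose by 1.26 ± 0.17 and Ltf, which encodes lactoferrin, fell by 1.42. Of 14 genes of tumour-associated neutrophils 5 fell and 1 rose, also when adjusted over the list alone (2 mainly of another class; camera adjusted p = 0.0640). The cathepsin Ctsb fell by 1.71, the haem oxygenase Hmox1 by 2.65 and the chemokine Ccl3 by 1.35.

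Lists of MHC class I (2 lower of 12), MHC class II, cell cycle, hypoxia (1 higher and 1 lower of 13) and immediate early genes (4 higher and 3 lower of 16) did not pass in neutrophil-like cells (camera adjusted p = 0.899 each). Adjusted over the list alone, 1 MHC class I gene was lower, and 4 immediate early genes were higher and 5 lower. Mainly of another class were 3 of the MHC class I, 7 of 7 MHC class II, 11 of 12 cell cycle and 1 of the immediate early genes. Medians and means differed in sign for immediate early genes (0.22 and -0.22) and hypoxia genes (0.09 and -0.07). The groups lay in different neutrophil clusters. A cluster led by Retnlg and S100a9 held 52.1% of the AOM PN and 3.94% of the Apc ICI cells. Its shares were 3.25%, 0.450% and 14.2% in Apc ICI 1, 2 and 3. Clusters led by Ifi27l2a with Ifit3 and by Cstb with Hmox1 held 39.1% and 34.3% of the Apc ICI cells, and 4.17% and 1.10% of the AOM PN cells (2.75% for the former without AOM PN 2).

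Monocyte/macrophage-like cells of AOM PN carried more Timp1, an inhibitor of matrix proteases, and less of a list of resident macrophage genes (camera adjusted p = 0.000270; adjusted p = 0.50 with an estimated correlation). Of 11064 genes 126 rose and 164 fell (edgeR adjusted p under 0.05), groups did not overlap for 27.5% against 10% by chance, and 93 calls were of genes mainly of another class. Timp1 rose from 57.3 ± 4.89 to 224 ± 42.8 CPM (1.97 ± 0.16, edgeR adjusted p = 0.00224), Eps8 by 1.82 ± 0.22 and Notch2 by 1.59 ± 0.18, and the lipoprotein lipase Lpl fell by 1.41. These 4 calls held whichever library was left out, and the other 16 of 20 named calls were lost in at least 1 such fit. Chil3 rose by 2.09 ± 0.40 (edgeR adjusted p = 0.122 without Apc ICI 2), Thbs1 by 1.19 ± 0.21 (0.125 without Apc ICI 2) and Fn1 by 0.82 ± 0.13 (0.117 without Apc ICI 2). The growth factor Igf1 fell by 2.45 (edgeR adjusted p = 0.119 without Apc ICI 2), and the monocyte antigen Ly6c2 by 1.38 (0.115 without Apc ICI 3). The phagocytosis bridging protein Mfge8 fell by 3.08 (by 2.39 without Apc ICI 2; edgeR adjusted p = 0.0530 without AOM PN 1). Without Apc ICI 2 only 17 genes rose and 22 fell.

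Classical monocyte genes were higher as a list (3 rose and 1 fell of 12) and resident macrophage genes lower (3 fell of 11), each with a camera adjusted p of 0.000270 (adjusted p = 0.50 with an estimated correlation). Adjusted over the list alone, 4 rose and 1 fell of the former, and 8 fell and 1 rose of the latter, and 2 members of each were mainly of another class. Interferon response and cell cycle genes were lower as lists, with the same camera adjusted p (adjusted p = 0.50 with an estimated correlation) and no member called (5 and 8 lower adjusted over the list alone). Of the 18 interferon members 6, and of the 21 cell cycle members 13, were mainly of another class. NF-κB targets were higher as a list with no member called (6 higher and 1 lower adjusted over the list alone; 4 of 17 mainly of another class; camera adjusted p = 0.00365; adjusted p = 0.50 with an estimated correlation). Immediate early genes (2 of 16, also adjusted over the list alone; 4 mainly of another class; camera adjusted p = 0.00825) and hypoxia genes (none of 14; 1 mainly of another class; 0.0186) were higher as lists. With an estimated correlation each of these 7 lists had an adjusted p = 0.50. Of 14 genes of lipid-associated macrophages 1 rose and 2 fell (3 and 3 adjusted over the list alone; 1 mainly of another class; camera adjusted p = 0.428), and no MHC class I or II gene was called (0.128 and 0.379). The NF-κB call was lost without AOM PN 1 (adjusted p = 0.0643) and the immediate early call without AOM PN 2 (0.386). The hypoxia call was lost without Apc ICI 1 (adjusted p = 0.25), Apc ICI 2 (0.0630), AOM PN 1 (0.184) or AOM PN 2 (0.0643). A cluster led by Apoe and C1qa held 47.2% of the Apc ICI and 12.4% of the AOM PN cells of this class. Clusters led by Plac8 with Chil3 and by Ccl24 with Arg1 held 27.03% and 22.1% of the Apc ICI and 47.1% and 39.4% of the AOM PN cells. Median depths of these clusters were 1429.5, 8516 and 9710 UMIs. Over the class, median depths were 7172, 2785 and 2790 UMIs in Apc ICI 1, 2 and 3. They were 6962, 9647.5 and 8519 in AOM PN 1, 2 and 3, and the part of depth in these shares was not tested. In AOM PN 1, 2 and 3 the Plac8 cluster held 55.6%, 60.2% and 28.8% and the Ccl24 cluster 23.4%, 29.97% and 61.6%, and each overlapped the Apc ICI range of 17.1% to 35.6% and 16.8% to 25.3%.

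T/NK-like cells of AOM PN carried more of the cytokine Il22, the chemokine Xcl1 and the integrin Itgae (CD103), and less of the inhibitory receptors Havcr2 (TIM-3) and Pdcd1 (PD-1). Of 10289 genes 108 rose and 128 fell (edgeR adjusted p under 0.05), groups did not overlap for 26.5% against 10% by chance, and 55 calls were of genes mainly of another class. The receptor gene Klri2 fell from 117 ± 13.8 to 21.8 ± 4.76 CPM (edgeR adjusted p = 0.000993) and Igfbp7 from 57.1 ± 4.35 to 13.9 ± 3.06 (0.00338). These 2 calls held whichever library was left out, and the other 22 named calls did not. Il22 rose by 2.47 ± 0.53 (1.74 without AOM PN 2 and 3.11 without Apc ICI 3; edgeR adjusted p = 0.186 without Apc ICI 1). Xcl1 rose by 2.43 ± 0.48 (edgeR adjusted p = 0.161 without Apc ICI 1) and Itgae by 1.43 ± 0.24 (0.111 without Apc ICI 3). Havcr2 fell by 1.36 and Pdcd1 by 0.96 (edgeR adjusted p = 0.143 and 0.176 without Apc ICI 1). Without Apc ICI 1 only 2 genes rose and 4 fell, and 5 rose and 10 fell without Apc ICI 3.

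MHC class II genes were higher in T/NK-like cells as a list (2 of 8 rose, 6 adjusted over the list alone, all mainly of another class; camera adjusted p = 0.00173; adjusted p = 0.595 with an estimated correlation). Genes of regulatory T cells were higher only as a list (1 of 12 rose; 5 rose and 1 fell adjusted over the list alone; 1 mainly of another class; adjusted p = 0.595 with an estimated correlation). Genes of type 17 and gamma-delta T cells were lower as a list (Il22 rose and Tcrg-C1 fell, of 14; 1 and 5 adjusted over the list alone), as were MHC class I genes (2 of 12 fell; 3 rose and 6 fell adjusted over the list alone). These 3 lists had a camera adjusted p of 0.0426 each, and all 4 had an adjusted p = 0.595 with an estimated correlation. Without Apc ICI 1 the adjusted p was 0.152 for regulatory T cells, 0.117 for type 17 cells and 0.117 for MHC class I. The regulatory call was also lost without AOM PN 3 (adjusted p = 0.239), the type 17 call without AOM PN 1 (0.105) or 2 (0.165), and the MHC class I call without Apc ICI 3 (0.0592) or AOM PN 3 (0.0986). Lists of exhaustion (2 lower of 11; camera adjusted p = 0.159), cytotoxic effectors (0.343), naive and memory cells (1 lower of 10; 0.220), interferon response (1 higher and 2 lower of 18; 0.0853), cell cycle (0.0559), hypoxia (0.343) and immediate early genes (2 higher of 16; 0.167) did not pass. Adjusted over the list alone, 1 exhaustion gene rose and 4 fell, 2 interferon genes rose and 5 fell, 1 naive gene rose and 2 fell, and 3 immediate early genes rose. Mainly of another class were 11 interferon, 7 immediate early, 5 of 13 hypoxia, 4 naive, 3 of 21 cell cycle, 1 exhaustion and 1 of 14 cytotoxic genes. A cluster led by Il17a and Il22 held 53.1% of the Apc ICI and 29.6% of the AOM PN cells of the class (19.3% without AOM PN 3), and one led by Tnfrsf4 held 34.9% and 46.0%. One led by Ccl5, Nkg7 and Xcl1 held 12.0% of the Apc ICI and 24.4% of the AOM PN cells. In AOM PN 1, 2 and 3 it held 37.2%, 26.95% and 10.8%, the last below each Apc ICI library (11.5% to 12.6%).

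In B-like cells the dehydrogenase Aldh7a1 and the interferon-induced gene Ifi27l2a fell in AOM PN. Of 4951 genes 25 rose and 19 fell (edgeR adjusted p under 0.05), groups did not overlap for 18.1% against 10% by chance, and 22 calls were of genes mainly of another class. Aldh7a1 fell from 69.7 ± 20.4 to 2.41 ± 2.10 CPM (edgeR adjusted p = 0.000806), whichever library was left out. Ifi27l2a fell by 1.38 (edgeR adjusted p = 0.0124, and 0.0884 without Apc ICI 2). Of 7 interferon response genes 4 fell, also when adjusted over the list alone (4 of the 7 mainly of another class; camera adjusted p = 1.6e-05; adjusted p = 0.229 with an estimated correlation), and the list call was lost without AOM PN 3 (adjusted p = 0.103). MHC class II genes were lower as a list with none of 8 called and 1 lower adjusted over the list alone (2 mainly of another class; camera adjusted p = 0.00529; adjusted p = 0.229 with an estimated correlation). That call was lost without Apc ICI 1 (adjusted p = 0.0560). MHC class I (2 higher and 1 lower adjusted over the list alone), cell cycle and hypoxia genes did not pass (camera adjusted p of 0.816, 0.816 and 0.217), with 6 of 7 hypoxia genes mainly of another class. Of 16 immediate early genes 1 rose (2 higher and 1 lower adjusted over the list alone; 8 mainly of another class; camera adjusted p = 0.836, downward against a median of 0.19). Without Apc ICI 2 only 3 genes rose and 2 fell.

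In dendritic-like cells 6 genes rose and 4 fell of 8685 (edgeR adjusted p under 0.05), and groups did not overlap for 18.9% of genes against 10% by chance. Timd4, a receptor for apoptotic cells, rose by 2.97 ± 0.38 and Actb, the cytoskeletal actin, by 0.63 ± 0.09, and Anxa3 fell by 1.11 (edgeR adjusted p = 0.0417 each). All 7 named calls were lost in at least 1 fit that left out a library; for these 3 the adjusted p was 0.0982, 0.255 and 0.185 without Apc ICI 2. EdgeR called 0 genes without Apc ICI 1, 2 or 3 or AOM PN 1, 1 without AOM PN 3 and 29 without AOM PN 2. With all libraries 1047 genes had an unadjusted p under 0.05, and DESeq2 called 48 higher and 27 lower. Interferon response genes were lower as a list with none of 18 called and 1 lower adjusted over the list alone (7 mainly of another class; camera adjusted p = 0.0206; adjusted p = 0.926 with an estimated correlation). That call was lost without Apc ICI 1 (adjusted p = 0.547), Apc ICI 3 (0.110) or AOM PN 3 (0.881). Cell cycle, MHC class I, MHC class II, hypoxia and immediate early genes did not pass (camera adjusted p of 0.916, 0.665, 0.665, 0.665 and 0.218), and the cell cycle test pointed up against a median of -0.02. Adjusted over the list alone, 1 MHC class I gene was lower and 1 hypoxia gene higher. Mainly of another class were 6 of 14 cell cycle, 5 of 14 hypoxia and 5 of 16 immediate early genes. A cluster led by Cst3 and H2-Ab1 held 47.5% of the Apc ICI and 70.4% of the AOM PN cells of the class, and one led by Ccl22 with Ccr7 held 47.8% and 21.5%.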

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

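All tests in this part were chosen after the data had been seen: those of differences between cell classes, of RNA from other classes and of other splits of the libraries. Each result below was singled out because the change between AOM PN and Apc ICI differed between an immune class and epithelial-like cells in a test of that difference. Of 15 such tests of the targeted genes 5 passed, and of 30 tests of lists 14 passed with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.0689.

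The log2 change of Trp53 was higher than in epithelial-like cells by 1.08 in T/NK-like cells (edgeR adjusted p = 0.00285), by 1.05 in monocyte/macrophage-like cells (0.00508) and by 1.32 in dendritic-like cells (0.00211). The log2 change of Notch1 differed by -1.20 in T/NK-like cells (edgeR adjusted p = 0.00175), and that of Apc by 1.24 in monocyte/macrophage-like cells (0.00219). On the same scale Notch1 ran at 52.7 to 54.4 in Apc ICI and 38.1 to 46.6 in AOM PN T/NK-like cells. Apc ran at 12.6 to 22.2 in Apc ICI and 27.9 to 32.8 in AOM PN monocyte/macrophage-like cells, a rise there.

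Interferon response genes differed from epithelial-like cells in 5 classes. The median difference was -0.81 in T/NK-like cells (camera adjusted p = 0.0375; adjusted p = 0.825 with an estimated correlation), -1.59 in B-like cells (1.66e-05; 0.324) and -1.59 in monocyte/macrophage-like cells (0.00180; 0.452). It was -1.01 in dendritic-like cells (camera adjusted p = 0.0106; adjusted p = 0.701 with an estimated correlation) and -2.15 in neutrophil-like cells (7.05e-06; 0.219). MHC class II genes differed by a median of -2.03 in B-like cells (camera adjusted p = 1.79e-10; adjusted p = 0.0689 with an estimated correlation) and -1.94 in monocyte/macrophage-like cells (1.1e-05; 0.291). They differed by -1.70 in dendritic-like cells (camera adjusted p = 3.39e-06; adjusted p = 0.221 with an estimated correlation) and -1.85 in neutrophil-like cells (0.000196; 0.219). MHC class I genes differed by -0.59 in T/NK-like cells (camera adjusted p = 0.0375; adjusted p = 0.825 with an estimated correlation), -0.53 in B-like cells (0.0488; 0.375) and -0.89 in monocyte/macrophage-like cells (0.0368; 0.452). Cell cycle genes differed by -1.48 in monocyte/macrophage-like cells (camera adjusted p = 3.07e-06; adjusted p = 0.322 with an estimated correlation). Immediate early genes differed by -0.57 in B-like cells (camera adjusted p = 0.00438; adjusted p = 0.324 with an estimated correlation).

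The summed level of 7 MHC class II genes rose by a log2 of 1.33 in AOM PN epithelial-like cells, and free RNA of immune cells is a candidate source. After the rise of 30 abundant monocyte/macrophage genes was taken off, 0.64 ± 0.20 (SE) was left, and 0.65 ± 0.27 and 1.01 ± 0.31 with other choices of genes. Those 30 genes included Ctss, 1 of the 7 class II genes, and Apoe, C1qa and C1qb. Resident macrophage genes were lower as a list in AOM PN, and so was the share of the cluster led by Apoe and C1qa. The 30 genes may thus understate the macrophage RNA in AOM PN, so this test cannot decide. For B cells 1.51 ± 0.36 and 1.65 ± 0.52 were left, for dendritic cells 2.07 ± 0.46 and 0.07 ± 0.37, and 1 choice of genes gave no value for each. By the rule that all 3 choices had to point one way, this test left both undecided. In a test added last, the rise needed 0.885% of the RNA level of monocytes and macrophages, 0.539% of dendritic and 0.702% of B cells. Their abundant genes stood at 0.587% to 1.02%, 1.06% to 1.38% and 0.246% to 0.312% in the AOM PN libraries, below the need in every library for B cells alone. These are levels, not rises. In Apc ICI the same genes averaged 0.488%, 2.02% and 0.319%, against 0.792%, 1.21% and 0.281% in AOM PN. A level above the need therefore does not show that such RNA rose enough. For B cells the level lay below the need and was on average no higher in AOM PN. With the 1.51 and 1.65 left above, this argues against B cell RNA as the whole source of the rise. The level test was chosen with these shares already seen, and a part from B cells stays open. A change within the epithelium between the models was not tested apart from these sources of RNA.

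The epithelial-like sums gave 4784 called genes and at most 1 in the other splits of the 6 libraries. The highest other split gave 1 against 236 in T/NK-like cells and 1 against 44 in B-like cells. It gave 0 against 290 in monocyte/macrophage-like cells, 0 against 10 in dendritic-like cells and 0 against 3039 in neutrophil-like cells. In each class 1 split, the real one, gave as many genes, and 10 splits are too few for a share under 0.05.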

How the results depend on the processing

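The tests with at least 1000 genes per cell, at 1% to 20% mitochondrial UMIs, with cells of at least 1500 UMIs thinned to 1500 and without erythroid-like cells were chosen after the results were seen; the other alternatives were listed before the data were examined. Of 228 counts of genes under all alternatives 130 were within 1.5 times the reported count, 33 were higher and 65 lower. Of 503 list calls 420 were kept and 83 lost. Of 3804 values of named genes 3326 kept direction and call, 424 lost the call, 39 gained one and 15 changed direction. Of 132 class shares 118 kept both, 8 lost a call, 5 gained one and 1 changed direction. Of 48 shares of cells with a UMI 44 kept their direction, whatever their size, and 4 changed it. The cause was not tested for the changes below, apart from fewer UMIs or cells in thinned sums and fewer samples without a library.

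With DESeq2, 252 genes rose and 235 fell in T/NK-like, 382 and 331 in monocyte/macrophage-like and 48 and 27 in dendritic-like cells, and 8 T/NK and 2 dendritic lists were called. With no filter on low counts the numbers were 502 and 338 in T/NK-like, 134 and 85 in B-like, 571 and 498 in monocyte/macrophage-like and 171 and 101 in dendritic-like cells, and Ascl2 turned to -0.057. With sums thinned to the smallest total, 1470 epithelial and 80 T/NK genes fell, 6 rose and 8 fell in B-like cells, 3 and 0 in dendritic-like cells, Lgr5 turned to 0.031, and 1 B and 0 dendritic lists were called. With doublets kept, 250 rose and 203 fell in T/NK-like and 101 and 55 in dendritic-like cells, 7 fell in B-like cells, Muc2 turned to 0.068, and 2 dendritic and 5 neutrophil lists were called. At resolution 0.5, 319 rose and 300 fell in T/NK-like and 3 and 2 in dendritic-like cells, 152 rose in B-like cells, Mcm4 in B-like cells turned to -0.077, and 1 T/NK list was called.

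With at least 1000 genes per cell, 105 genes fell in monocyte/macrophage-like cells, 0 rose and 0 fell in dendritic-like cells, and 12 epithelial lists were called. With 1% to 20% mitochondrial UMIs, 292 rose and 296 fell in monocyte/macrophage-like, 1 and 1 in dendritic-like and 153 and 263 in neutrophil-like cells, Apc in epithelial-like cells turned to 0.068, and 0 dendritic lists were called. With only cells of at least 1500 UMIs, each thinned to 1500, 1220 rose and 926 fell in epithelial-like, 51 and 71 in T/NK-like, 6 and 9 in B-like, 79 and 100 in monocyte/macrophage-like, 13 and 16 in dendritic-like and 894 and 1023 in neutrophil-like cells. There Apc turned to 0.0022 and Ascl2 to -0.31 in epithelial-like cells, Cenpa to 0.21 and P4ha1 to -0.15 in dendritic-like cells, and 0 dendritic lists were called. With an estimated correlation 0 lists were called in each of 6 classes, and with fry 11 in epithelial-like cells and 0 in T/NK-, B-, monocyte/macrophage- and dendritic-like cells. Among the epithelial lists, fry called some that camera did not, all upward. They were crypt base stem cell markers (fry adjusted p = 0.00780), YAP/TAZ targets (0.0151), and fetal and regenerative genes and p53 targets (0.0411 each). The verdict on these lists thus depended on the test. In neutrophil-like cells fry called 2 lists, NF-κB targets (adjusted p = 0.0238) and tumour-associated neutrophils (0.0168), and lost the interferon and circulating neutrophil lists (0.0929 each). The plasma share was 2.10 (edgeR adjusted p = 0.117) with TMM over classes, 2.04 (0.0758) at resolution 2 and 2.17 (0.0548) among cells outside the epithelial-like class. With at least 500 genes per cell the epithelial share was -1.56 (edgeR adjusted p = 0.0418) and the erythroid share -2.98 (0.0347). Without erythroid-like cells the mast share was 4.82 (edgeR adjusted p = 5.75e-05). At 3000 UMIs the difference in cells with a UMI was -5.24 points for Lgr5 (exact permutation p = 0.4), 0.394 for Ascl2, 38.1 for Ly6a, 11.9 for Anxa1, 16.0 for Clu and 6.85 for Mki67 (exact permutation p = 0.1 for the last 4). Without thinning it was -15.1 points for Lgr5, -11.8 for Ascl2, 6.97 for Ly6a, -16.0 for Anxa1, -8.05 for Clu and -1.65 for Mki67.

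With the replicate block, 33 genes rose and 38 fell in monocyte/macrophage-like cells, 0 fell in dendritic-like cells, and the plasma share was 2.12 (edgeR adjusted p = 0.0731). Samples of the same number had correlations of -0.127, 0.202 and -0.187 in epithelial-like cells, and not every sample correlated best with its own number, so the replicate block has no basis in the data.

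With each library left out in turn, 1954 to 2354 genes rose and 1693 to 2223 fell in epithelial-like cells, 2 to 198 and 4 to 265 in T/NK-like, 3 to 51 and 2 to 34 in B-like, 17 to 232 and 22 to 167 in monocyte/macrophage-like, 0 to 20 and 0 to 9 in dendritic-like and 591 to 1391 and 878 to 1519 in neutrophil-like cells. Lists called numbered 6 to 11 in epithelial-like, 1 to 7 in T/NK-like, 1 to 2 in B-like, 5 to 8 in monocyte/macrophage-like, 0 to 2 in dendritic-like and 3 to 4 in neutrophil-like cells. In epithelial-like cells the change ran from -0.40 to 0.17 for Lgr5, -0.29 to 0.33 for Ascl2, -0.017 to 0.36 for Cdkn1a and -0.18 to 0.56 for Anxa1. The log2 change of the share ran from -2.21 to -0.39 for B-like, 1.18 to 1.90 for T/NK-like, 0.99 to 1.6 for dendritic-like, -1.15 to -0.67 for epithelial-like and -3.32 to -1.39 for erythroid-like cells. It ran from 4.40 to 5.62 for mast-like, 0.68 to 1.10 for monocyte/macrophage-like, -0.53 to 0.11 for neutrophil-like and 1.53 to 2.59 for plasma-like cells. The difference in cells with a UMI ran from -3.73 to -1.56 points for Lgr5, -1.86 to -0.344 for Ascl2, 13.6 to 15.9 for Ly6a, 0.956 to 6.65 for Anxa1, 5.48 to 12.2 for Clu and 3.80 to 8.55 for Mki67.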

Other observations

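The genes and tests in this part were chosen after the data had been seen. Only the list of mast markers and the setting with class sums thinned to 1 total were set beforehand. The rules for reading them were written afterwards. Mast-like cells of AOM PN carried the mucosal proteases Mcpt1 and Mcpt2 at 69847 ± 16152 and 76075 ± 17916 CPM (SD, n = 3), and Mcpt4 and Cma1, proteases of connective tissue mast cells, at 6064 ± 1369 and 8497 ± 3585. The tryptase Tpsb2 was at 9571 ± 1181 CPM, carboxypeptidase Cpa3 at 5555 ± 635, the serotonin-making enzyme Tph1 at 1721 ± 297 and the chemokine Ccl2 at 1373 ± 550. The IgE receptor chain Fcer1a was at 1372 ± 289 CPM, the receptor Kit at 748 ± 111, Il13 at 212 ± 148 and Il4 at 88.0 ± 18.4. A cluster led by mast proteases with histone genes such as Hist1h2ae held 457 AOM PN and 2 Apc ICI cells, 12.3% and 3.77% of the class. Both Apc ICI cells came from Apc ICI 2. The share of this cluster was 3.85%, 6.82% and 16.7% in AOM PN 1, 2 and 3, and 4.34% in AOM PN without AOM PN 3. The 14, 21 and 18 mast-like cells of Apc ICI 1, 2 and 3 had median depths of 1781, 912 and 1060 UMIs, against 3418, 8196 and 9113 in AOM PN 1, 2 and 3.

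In a comparison across classes, 24 genes were called in the same direction in at least 4 of 6 classes, 12 higher and 12 lower in AOM PN. The classes come from the same 6 libraries, so these calls are not independent, and no chance value is given. The ranges of log2 changes below cover all classes in which a gene was tested, called or not. Gm8797 was higher in 6 classes (2.49 to 3.77), and Mcpt1 (4.53 to 6.36), Mcpt2 (4.94 to 6.57) and Rpgrip1 (0.62 to 1.75) in 5. Among those higher in 4 were Ifrd1 (0.49 to 1.48) and the AP-1 member Jund (0.54 to 0.94). Among those lower in 4 classes were Wif1 (-5.78 to -5.01), Nkd1 (-3.22 to -2.38), the growth factor Ptn (-5.07 to -3.82) and Spink4 (-4.86 to -2.89). The class with the highest level was mast-like for Mcpt1 and Mcpt2 and epithelial-like for Wif1, Nkd1, Ptn and Spink4. In T/NK-, monocyte/macrophage- and neutrophil-like sums, 30 abundant epithelial genes stood at 1.57%, 1.24% and 1.62% of their epithelial level in Apc ICI. In AOM PN they stood at 1.09%, 0.678% and 0.930%. Whether free epithelial RNA made the falls of Wif1, Nkd1, Ptn and Spink4 in immune classes was not tested.

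Mast proteases were higher in sums of the other classes, and free RNA of mast cells is a candidate source. Mast genes stood at 0.0979% of their mast level in Apc ICI and 1.45% in AOM PN epithelial-like sums, and at 0.0579% and 0.598% in monocyte/macrophage-like sums. The correlation of 30 mast genes with the mast-like cells of the library ran from 0.432, in dendritic-like cells of AOM PN 2, to 0.970, which decides neither way. Gene choice was tried in 3 forms and the statistic in 2, with lowest values of 0.157 and 0.446 in the other forms. By the median, 0.880, 0.485 and 0.875 in the 3 forms, with thresholds set along with it, the first and last would have been read in favour of this source, so it stays open.

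The larger mast-like share was also read without clusters, which argues against clustering or naming as its source. Mast markers took 0.0127%, 0.0172% and 0.0416% of the non-haemoglobin UMIs of all kept cells in Apc ICI 1, 2 and 3. In AOM PN 1, 2 and 3 they took 1.97%, 0.706% and 7.47%. The log2 ratio between the lowest AOM PN and the highest Apc ICI value was 4.08. These sums cover only barcodes that passed the filters and were not removed as doublets. A difference between the models, and one of dissociation or sorting, were not told apart by any test.

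The depth of epithelial-like cells differed between the groups, which could have made calls. With class sums thinned to 1 total, 80.6% of the called genes tested again stayed called in the same direction (3062 of 3797), and with only the cells of at least 1500 UMIs, each thinned to 1500, 67.5% (1909 of 2829). The latter changed the cells as well as their depth, leaving out 584 Apc ICI and 1150 AOM PN cells. The former made the totals of the sums equal, not the UMIs per cell. For the genes tested again, both argue against unequal numbers of UMIs as the whole cause, and a part from depth stays open. The rest of the 4784 called genes could not be tested again. Thinning does not change the share of free RNA in a cell or its quality, so neither test covers causes that go with low depth.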
